A study of Homo sapiens with 6 samples.

How the data were processed

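Poly(A) RNA of A549 cells was sequenced from 3 control libraries and 3 libraries of cells given TGFβ1 at 10 ng/mL for 48 h, and samples were grouped by their titles. Per the labels' protocols, mRNA was selected with oligo(dT) beads and made into paired-end libraries that mark the strand with dUTP. The values are FPKM (fragments scaled to gene length and to mapped fragments) that the authors deposited for 34752 genes with coordinates on GRCh38. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6 were used, and DESeq2 and edgeR are named there by the submitters with no stated role. The options of each tool, whether counting used the strand and how transcript values were joined into gene values are not given in the sources used here. Antisense and overlapping genes are therefore uncertain, as are near-identical paralogs. Of the table's gene identifiers, 32229 are in GENCODE 29, and 81.9% of these have the same start or end there, while 8862 genes carry no symbol.

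The table holds FPKM and no counts, so the sequencing depth of each library is unknown and no counting interval can be given. Low values showed no steps of whole reads. The precision is that seen between libraries: among genes of at least 10 FPKM the median coefficient of variation was 2.76% in control (3647 genes) and 2.48% in TGFβ1 libraries (3572 genes). The labels call the samples biological replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate numbers were not treated as pairs. No library was a copy of another: at most 9 of the tested genes had identical values in any 2 libraries of a group.

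Genes with FPKM of at least 1 in 3 or more libraries were tested (12121 genes). Log2(FPKM + 1) was fitted on the 2 groups with limma 3.58.1 in R 4.3.3, with a mean-variance trend and a robust prior (statmod 1.5.0). P-values were Benjamini-Hochberg adjusted over all genes tested, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. All adjusted p-values given for genes are from this limma fit unless another setting is named. The study states an unpaired two-sample test on FPKM of chosen genes; the moderated fit was preferred because 3 libraries per group estimate a gene's spread poorly, and the stated test was run as an alternative. Values were read with the R package data.table, version 1.17.8, and plots drawn with matplotlib 3.10.9 in Python 3.11.15.

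The gene lists, tests and alternatives were fixed before the data were examined. The 31 lists were SMAD2/3 targets, BMP-SMAD targets, TGFβ ligands and receptors, EMT transcription factors, mesenchymal markers, epithelial junction genes, fibrillar matrix, basement membrane, collagen modifying enzymes, matrix proteases, integrins, actin cytoskeleton, proliferation, senescence, alveolar genes, airway and mucous genes, aberrant basaloid genes, NRF2 targets, NF-kB and inflammatory genes, interferon-stimulated genes, unfolded protein and integrated stress responses, cholesterol and fatty acid synthesis, hypoxia and glycolysis, pulmonary fibrosis risk genes, DNA methylation machinery, WNT pathway, fibroblast, endothelial and immune markers, mitochondrially encoded genes, and heat shock and immediate early genes. Each was tested against all other genes with limma's camera (preset correlation 0.01) adjusted over lists, beside camera with an estimated correlation and fry, whose p asks only whether a list's own genes move one way.

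Named genes followed a fixed rule. Its first part took the 10 genes with a symbol that rose most and the 10 that fell most, with an adjusted p under 0.05, a mean of at least 1 FPKM in the higher group and libraries that do not overlap between groups. Its second part took up to 4 members per list past the threshold with the largest absolute change. Its last part named 20 genes whatever their result: TGFBI, SMAD7, PMEPA1, CDH1, EPCAM, CDH2, VIM, FN1, ACTA2, COL1A1, SNAI2, ZEB1, MUC5B, TERT, DSP, DNMT1, MKI67, SFTPC, NKX2-1 and 1 other. Some genes under this rule are not reported here. Genes named outside the rule are members that went against their list or did not pass, paralogs, reference genes, regulators of NRF2, mitochondrial ribosomal RNAs and genes below the filter, and were chosen after their values were seen.

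The same steps were tested on simulated data with the control means and spread of each gene, with 200 of 12121 genes changed. Simulated genes varied independently, and far fewer changed than the 61.8% called in the real data. They recovered 86% of 100 changes of 0.5 and 99% of 100 changes of 1 on the log2 scale, with 11 false calls among 196. Camera called 5 of 5 shifted lists and 0 of 26 others, but these lists held random genes with no correlation between members. They do not show how often camera errs on real lists, whose members can be correlated. Alternatives were other pseudocounts (0.1 and 0.01), no filter, a filter of FPKM at least 5, median-ratio, quantile and fixed-sum scaling, limma with no trend or robust prior, the study's test, the replicate number as a block and each library left out. Alternatives planned for counts did not apply. Symbol families, single-transcript genes and mitochondrial genes left out were added after the data were seen.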

Results

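Polyadenylated RNA was sequenced from A549 cells, an established line derived from a human lung adenocarcinoma with features of alveolar epithelium. The series title concerns epigenetic drivers of idiopathic pulmonary fibrosis, and the comparison asks which mRNAs differ between A549 cells given TGFβ1, a cytokine that drives fibrosis and epithelial to mesenchymal transition, and control cells. There were 3 control libraries and 3 libraries from cells given TGFβ1 at 10 ng/mL for 48 h. A time is recorded here only for the TGFβ1 samples, so whether the controls were matched in time is not known. Expression was given as FPKM for 34752 genes on GRCh38, so the depth of each library is unknown. The FPKM of all genes summed to 287939 ± 477 in control and 265206 ± 895 in TGFβ1 libraries (mean ± SD, n = 3). Genes of the mitochondrial chromosome made up 33.7% ± 0.317 of that sum in control and 30.4% ± 0.257 in TGFβ1 libraries. Neither measure overlapped between the groups, where an exact two-sided permutation test of 3 against 3 cannot give a p below 0.1. Pearson correlations of log2(FPKM + 1) across the tested genes were 0.993 to 0.994 within groups and 0.922 to 0.925 between groups, and the first principal component held 89.5% of the variance and separated the groups.

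TGFβ1 raised lists of fibrillar matrix, collagen modifying, integrin and actin genes and lowered NRF2 targets, and each of these passed with an estimated correlation (adjusted p = 0.0486). Epithelial genes went both ways, with more falls than rises, and their list did not pass that test (adjusted p = 0.121). MMP2, a gelatinase, rose from 0.966 ± 0.0933 to 57.9 ± 1.63 FPKM (mean ± SD, n = 3, as for all levels that follow), a log2 change of 4.91 (SE 0.04, adjusted p = 5.84e-11). GPX2, a glutathione peroxidase, fell from 98.9 ± 1.40 to 0.834 ± 0.357 FPKM, and ALDH3A1, an aldehyde dehydrogenase, from 310 ± 5.51 to 7.82 ± 0.560 FPKM. Among 12121 genes tested, 3120 rose and 4370 fell, together 61.8%. A change of at least 2-fold was estimated for 862 of them, of which 398 rose and 464 fell.

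The 10 genes that rose most had log2 changes between 4.27 and 4.91. They included MMP2 (chromosome 16, 55389700 to 55506239), NPTX1 (chromosome 17, 80466834 to 80476607), IGFL1, CGB8, R3HDML, TNFAIP6, LCE3D and COL1A1 (chromosome 17, 50184101 to 50201632). NPTX1, a neuronal pentraxin, went from 5.26 ± 0.480 to 171 ± 2.04 FPKM. COL1A1, the alpha 1 chain of type I collagen, went from 1.87 ± 0.222 to 54.2 ± 1.16 FPKM, a log2 change of 4.27 (SE 0.05, adjusted p = 3.02e-10). CGB8, a chorionic gonadotropin beta gene, was listed at 42.8 ± 2.13 FPKM with TGFβ1, but it can share reads with the near-identical CGB5 and CGB3, which also rose, with log2 changes of 3.47 and 3.15. LCE3D, with a log2 change of 4.35, can likewise share reads with LCE3E, which rose by 3.56 on the log2 scale.

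The 10 genes that fell most had log2 changes between -3.63 and -5.79. GPX2 (chromosome 14, 64939152 to 64942746) fell by 5.79 on the log2 scale (SE 0.14, adjusted p = 4.67e-07) and ALDH3A1 (chromosome 17, 19737984 to 19748943) fell by 5.14 (SE 0.04, adjusted p = 5.94e-11). DKK1 (chromosome 10, 52314281 to 52317657), which encodes a secreted WNT antagonist, fell from 229 ± 5.34 to 8.81 ± 0.699 FPKM. AGR2 (chromosome 7, 16791811 to 16833433), a disulfide isomerase of mucus-producing cells, fell from 26.6 ± 0.364 to 0.212 ± 0.0513 FPKM. The others were TM4SF4, TM4SF20, PDK4, RTN4RL2, the chemokine gene CXCL5 and SUSD2. PDK4, a kinase that inhibits pyruvate dehydrogenase, fell from 22.7 ± 0.458 to 0.722 ± 0.0739 FPKM.

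The groups' libraries did not overlap for 8200 genes, 67.7% of those tested, where chance gives 10%. Because the FPKM sums differed, the balance of rises and falls depended on the scaling: rises made up 41.7% of changed genes on FPKM as given, 49.8% after median-ratio scaling, 50.5% after quantile normalization and 60.4% after scaling to a fixed sum, with 3739, 3805 and 4618 rises against 3775, 3723 and 3027 falls. Scaling to a fixed sum moved the median log2 change of all genes from -0.04 to 0.06, so small changes are relative to that choice. Of the 862 genes with a 2-fold change, 862, 862 and 861 stayed changed in the same direction under those scalings. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes near 0. The genes that rose and fell most were ranked on that scale, so their order depends on it. By the ratio of mean FPKM, TGFβ1 over control, SPDEF (0.00278) and MUC5AC (0.00593) fell further than SUSD2 (0.0598).

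**Figure D1:**
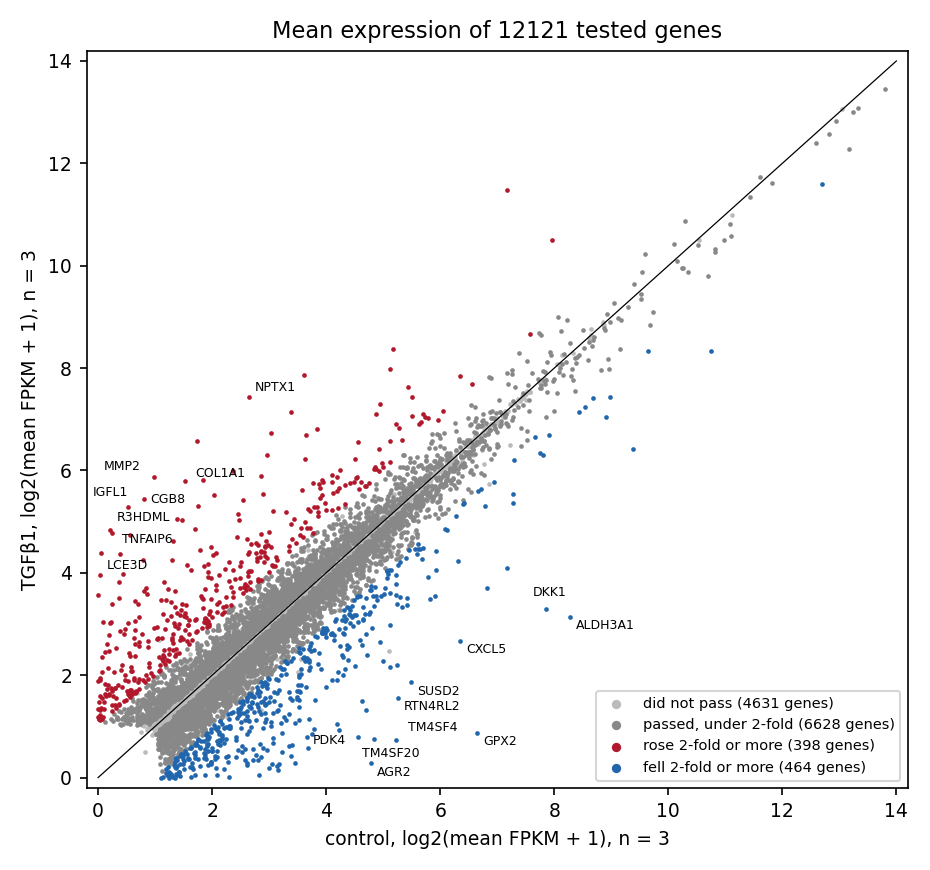
Mean expression in control (x axis) and TGFβ1 libraries (y axis), each as log2(mean FPKM + 1) of 3 libraries, with one point per tested gene, the diagonal marking no change, and genes of large change labelled. The 398 genes that rose at least 2-fold lie above the diagonal and the 464 that fell lie below it.

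Targets and feedback genes of SMAD2 and SMAD3, the transcription factors activated by TGFβ receptors, rose as a group: of 20 tested members 18 rose and 2 fell (median log2 change 1.30, camera adjusted p = 1.12e-09, 0.0486 with an estimated correlation). IL11, an interleukin, rose from 11.2 ± 0.264 to 231 ± 2.16 FPKM, and CCN2, a matricellular growth factor gene, from 9.44 ± 0.404 to 140 ± 4.11 FPKM. PMEPA1 and SMAD7, which encode feedback inhibitors of the pathway, had log2 changes of 2.86 (SE 0.03) and 1.31 (SE 0.04). TGFBI (chromosome 5, 136028988 to 136063818) rose from 249 ± 6.82 to 1444 ± 8.26 FPKM. The members that fell were TGIF1, a repressor of SMAD transcription, by 0.38 and TSC22D1, a leucine zipper gene, by 1.13 on the log2 scale. For 26 of the 31 lists the counts adjusted over the list alone were those given here, and the other 5 are given at their lists. The median, mean and test differed in sign for 0 lists.

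Among ligands, receptors and activators of TGFβ, 10 of 14 tested members rose and 4 fell (median log2 change 0.41, camera adjusted p = 0.00551, but adjusted p = 0.154 with an estimated correlation). TGFBR1, a receptor kinase, rose from 7.35 ± 0.0434 to 35.9 ± 0.647 FPKM, while TGFBR2, SMAD3, TGFBR3 and SMAD2 fell, with log2 changes of -1.01, -1.02, -1.32 and -0.30. LTBP3, which binds latent TGFβ, rose from 14.4 ± 0.379 to 54.0 ± 0.859 FPKM, and FURIN, a protease that processes TGFβ precursors, from 17.9 ± 0.657 to 63.0 ± 0.333 FPKM. Targets of BMP-activated SMADs moved down: 7 of 8 tested members fell and 1, ID3, rose by 0.26 on the log2 scale (median -1.07, camera adjusted p = 0.00329). With an estimated correlation the list did not pass (adjusted p = 0.114). The median was -1.05 after median-ratio scaling and -0.99 after quantile normalization. It was -1.65 after scaling to a fixed sum, which also lowers the weight of the pseudocount in low genes. ID2, an inhibitor of helix-loop-helix factors, fell from 42.0 ± 1.56 to 10.3 ± 0.664 FPKM and BMP4 from 4.94 ± 0.262 to 1.17 ± 0.0966 FPKM. With a filter of FPKM at least 5 the BMP list no longer passed (adjusted p = 0.175). Among its members below the filter, fitted with no filter, HEY1 rose from 0.136 to 0.456 FPKM (adjusted p = 0.00333). BMP2 rose there from 0.333 to 0.845 FPKM (adjusted p = 0.0164), while SMAD9 and GATA2 did not pass.

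Mesenchymal markers rose, with 7 of 8 tested members up and 1 down (median log2 change 1.22, camera adjusted p = 0.000126, 0.0490 with an estimated correlation). TAGLN, an actin-binding protein of smooth muscle, went from 1.48 ± 0.170 to 23.7 ± 1.28 FPKM. SPARC, a matricellular protein gene, went from 4.51 ± 0.180 to 34.4 ± 1.66 FPKM. CDH2, which encodes N-cadherin, rose from 7.16 ± 0.175 to 21.7 ± 0.810 FPKM, VIM from 212 ± 5.37 to 413 ± 2.82 FPKM and FN1 from 60.9 ± 2.60 to 104 ± 2.11 FPKM. S100A4, a calcium-binding protein used as a fibroblast marker, was the member that fell, from 154 ± 2.35 to 45.3 ± 1.80 FPKM. ACTA2, the smooth muscle actin gene, was below the expression filter at 0.917 ± 0.126 and 1.02 ± 0.240 FPKM.

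Of 22 tested epithelial junction and identity genes, 15 fell, 6 rose and 1 did not pass (median log2 change -0.92, camera adjusted p = 0.0278, but adjusted p = 0.121 with an estimated correlation). CDH1 (chromosome 16, 68737292 to 68835537), which encodes E-cadherin, fell from 17.8 ± 0.776 to 0.911 ± 0.0922 FPKM (log2 change -3.30, SE 0.05, adjusted p = 7.27e-10). ELF3, an epithelial transcription factor, fell from 23.6 ± 0.305 to 1.81 ± 0.163 FPKM, KRT19 from 9.96 ± 0.326 to 1.09 ± 0.0898 FPKM and CLDN2, a claudin, from 38.2 ± 0.868 to 10.5 ± 0.320 FPKM. EPCAM, an epithelial adhesion molecule, had a log2 change of -0.87 (SE 0.07). The members that rose were CLDN4, another claudin, by 1.68 on the log2 scale, and TJP1, JUP, KRT7, MAP7 and F11R. DSP, the desmosomal protein desmoplakin, had a small fall, by 0.16 on the log2 scale (adjusted p = 0.00530), which did not pass after scaling to a fixed sum (adjusted p = 0.224). With a filter of FPKM at least 5 the list no longer passed (adjusted p = 0.172).

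Of 10 tested transcription factors of epithelial to mesenchymal transition, 6 rose, 2 fell and 2 did not pass (median log2 change 0.35, camera adjusted p = 0.0221, but adjusted p = 0.121 with an estimated correlation). SNAI1, a repressor of E-cadherin, rose from 3.06 ± 0.239 to 19.4 ± 0.712 FPKM. ETS2 and SOX4 rose by 1.38 and 1.12 on the log2 scale, and ZEB1 rose from 2.71 ± 0.215 to 4.28 ± 0.0657 FPKM. TWIST2 fell from 6.19 ± 0.124 to 3.36 ± 0.245 FPKM, and ETS1 fell by 0.11 on the log2 scale. TWIST1 and HMGA2, at log2 changes of -0.05 and 0.03, did not pass. SNAI2 was below the expression filter, at 0.0903 ± 0.0475 FPKM in control and 0.945 ± 0.116 FPKM with TGFβ1.

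**Figure D2:**
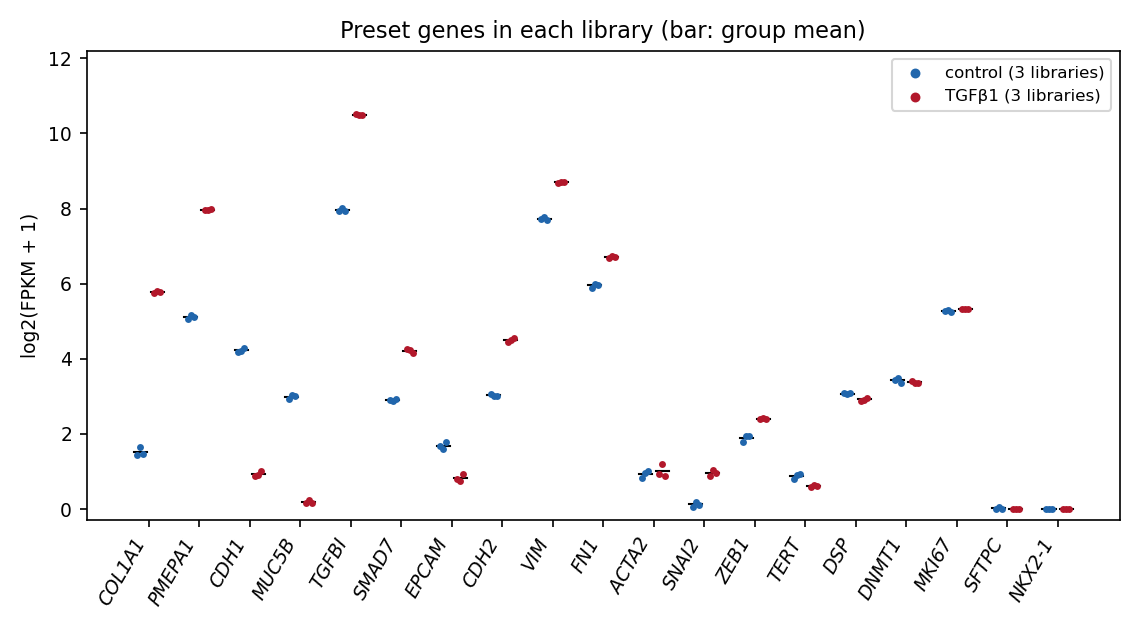
log2(FPKM + 1) of genes named in advance (x axis) in each library, with blue points for the 3 control and red points for the 3 TGFβ1 libraries and a bar at each group mean. CDH1 went from 17.8 to 0.911 FPKM and TGFBI from 249 to 1444 FPKM, while ACTA2, SFTPC and NKX2-1 stayed near 1 FPKM or below in both groups.

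Fibrillar and interstitial matrix genes rose, with 15 of 18 tested members up and 3 down (median log2 change 1.10, camera adjusted p = 4.89e-07, 0.0486 with an estimated correlation). SPOCK1, a matrix proteoglycan, rose from 2.57 ± 0.0818 to 55.5 ± 1.11 FPKM, and THBS1, which encodes thrombospondin, from 4.18 ± 0.113 to 62.2 ± 0.978 FPKM. The members that fell were COL12A1, FBN2 and EFEMP1, with log2 changes of -0.42, -0.72 and -0.76. Of 17 tested collagen modifying and crosslinking enzymes, 14 rose, 1 fell and 2 did not pass (median log2 change 0.62, camera adjusted p = 4.89e-07, 0.0486 with an estimated correlation). P4HA3, a subunit of collagen prolyl hydroxylase, rose from 11.4 ± 0.598 to 73.9 ± 0.298 FPKM, BMP1, a procollagen protease, from 9.38 ± 0.420 to 30.0 ± 0.298 FPKM and TGM2, a transglutaminase, from 54.3 ± 0.552 to 130 ± 1.56 FPKM. SERPINH1, a collagen chaperone, fell by 0.28 on the log2 scale, and P3H2 and PCOLCE did not pass, at log2 changes of 0.06 and -0.08.

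Basement membrane genes moved unevenly: 13 of 18 tested members rose, 4 fell and 1 did not pass (median log2 change 0.38, camera adjusted p = 0.000543, but adjusted p = 0.144 with an estimated correlation), and adjusted over the list alone 13 rose and 5 fell. COL4A1 and COL4A2, type IV collagen chains, rose from 7.18 ± 0.325 to 106 ± 2.53 FPKM and from 13.2 ± 0.262 to 111 ± 2.13 FPKM. LAMA3, a laminin chain, fell by 1.41 on the log2 scale, as did COL4A6 by 0.76, LAMB2 by 0.34 and COL4A5 by 0.32. Of 15 tested matrix proteases, plasminogen activators and their inhibitors, 10 rose and 5 fell (median log2 change 1.17, camera adjusted p = 0.00231, but adjusted p = 0.0755 with an estimated correlation). ADAM19, a membrane metalloproteinase, rose from 2.38 ± 0.0889 to 38.5 ± 0.665 FPKM and SERPINE2, a protease inhibitor, from 6.83 ± 0.376 to 77.6 ± 0.470 FPKM. MMP7, or matrilysin, fell from 11.8 ± 0.560 to 0.488 ± 0.185 FPKM, and MMP24, MMP15, ADAM12 and MMP17 also fell.

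Integrins and the actin cytoskeleton rose. Of 12 tested integrin genes 9 rose, 2 fell and 1 did not pass (median log2 change 1.00, camera adjusted p = 8.33e-05, 0.0486 with an estimated correlation). ITGA11, the alpha chain of a collagen receptor, rose by 3.45 on the log2 scale, ITGA5, the alpha chain of the fibronectin receptor, from 6.48 ± 0.187 to 20.2 ± 0.193 FPKM and ITGAV from 14.7 ± 0.548 to 40.2 ± 0.121 FPKM. ITGB5 and ITGB4 fell by 0.70 and 0.17 on the log2 scale, and ITGA6 did not pass, at 0.04. Of 20 tested actin cytoskeleton and contractile genes 18 rose and 2 fell (median log2 change 0.78, camera adjusted p = 3.68e-09, 0.0486 with an estimated correlation). TPM1, a tropomyosin, rose from 29.7 ± 1.28 to 157 ± 0.377 FPKM, and PDLIM7 and MYO10, an actin-associated protein and a myosin, by 1.76 and 1.34 on the log2 scale. MYLK, the myosin light chain kinase, and PDLIM5 fell by 1.08 and 1.14.

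Genes of aberrant basaloid cells, an epithelial state described in fibrotic lungs, rose in 12 of 16 tested members, fell in 3 and did not pass in 1 (median log2 change 0.86, camera adjusted p = 0.000126, 0.0486 with an estimated correlation). The list holds matrix and mesenchymal genes named above, among them COL1A1 and CDH2. Its basal members KRT17, KRT5 and TP63 were below the expression filter, so the call does not cover them. Fitted with no filter, TP63 rose from 0.259 to 0.897 FPKM (adjusted p = 0.00119) and KRT17 from 0.0160 to 0.151 FPKM (adjusted p = 0.0164). In that fit KRT5 did not pass. The members that fell were MMP7, GDF15, a stress-induced cytokine, and PTGS2, which encodes cyclooxygenase. GDF15 went from 9.57 ± 2.07 to 0.560 ± 0.0804 FPKM and PTGS2 from 8.39 ± 0.689 to 0.839 ± 0.135 FPKM.

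Targets of NRF2, the transcription factor of the antioxidant and detoxification response, fell: of 25 tested members 24 fell and 1 rose (median log2 change -1.22, camera adjusted p = 6.53e-12, 0.0486 with an estimated correlation). Besides GPX2 and ALDH3A1, AKR1C2, an aldo-keto reductase, fell from 669 ± 10.2 to 85.2 ± 2.02 FPKM and AKR1C1 from 112 ± 3.63 to 12.1 ± 0.518 FPKM. AKR1C1 and AKR1C2 are near-identical and can share reads. HMOX1, which encodes heme oxygenase, was the member that rose, by 0.24 on the log2 scale (SE 0.04, adjusted p = 0.000634). A fall of at least 2-fold was estimated for 14 members.

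**Figure D3:**
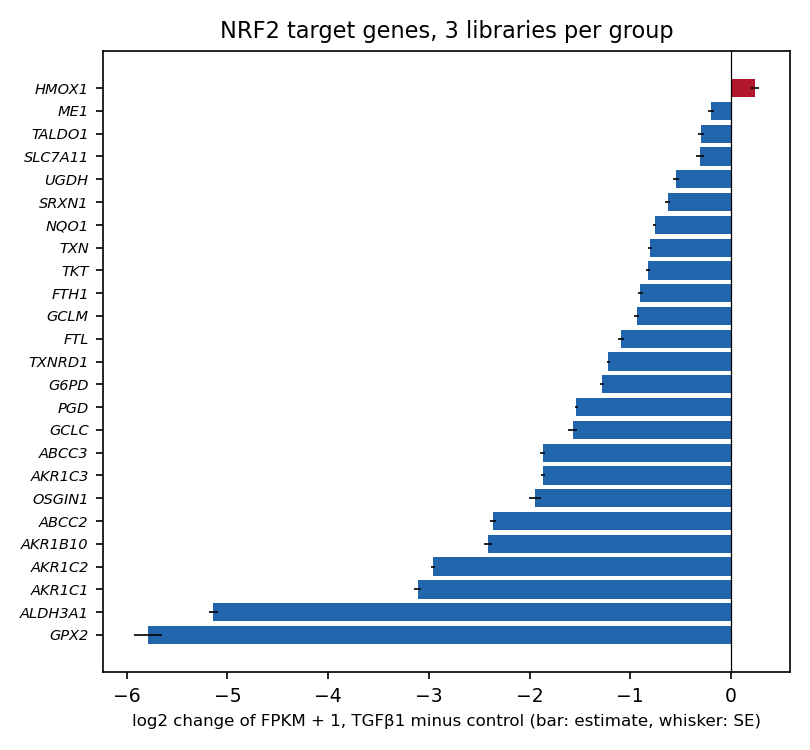
log2 change of FPKM + 1, TGFβ1 minus control (x axis), of the 25 tested NRF2 targets (y axis), with 3 libraries per group, bars for the estimate and whiskers for its SE. The list runs from GPX2 at -5.79 to HMOX1 at 0.24, with 24 members below 0.

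NF-kB and inflammatory genes fell in 11 of 13 tested members and rose in 2 (median log2 change -1.23, camera adjusted p = 0.00216, but adjusted p = 0.154 with an estimated correlation). CXCL5 fell from 80.3 ± 3.74 to 5.39 ± 0.352 FPKM, CXCL1, another neutrophil chemokine, from 10.6 ± 0.613 to 1.84 ± 0.537 FPKM and C3, the complement component, from 6.41 ± 0.385 to 0.483 ± 0.00878 FPKM. CCL2, a monocyte chemokine, and LIF, a cytokine, rose by 1.13 and 0.42 on the log2 scale. With a filter of FPKM at least 5 the list no longer passed (adjusted p = 0.0566). Of 10 tested interferon-stimulated genes 3 rose, 4 fell and 3 did not pass (camera adjusted p = 0.971), and adjusted over the list alone 4 rose and 4 fell. Its median log2 change was -0.00 and turned positive under each of the 3 scalings, up to 0.10. OAS1, an antiviral enzyme, fell from 2.94 ± 0.184 to 0.853 ± 0.0502 FPKM, while HLA-B rose from 0.844 ± 0.159 to 2.03 ± 0.0887 FPKM. The 6 transcripts listed for HLA-B are only of the retained intron type, so this value may not measure its coding mRNA.

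Of 20 tested genes of the unfolded protein and integrated stress responses 7 rose, 11 fell and 2 did not pass, which camera did not call (adjusted p = 0.612), and adjusted over the list alone 7 rose and 12 fell. TRIB3, a pseudokinase of the integrated stress response, fell from 21.1 ± 1.81 to 6.81 ± 0.378 FPKM and DDIT3, which encodes the stress transcription factor CHOP, from 4.71 ± 0.103 to 1.40 ± 0.152 FPKM. The members that rose were endoplasmic reticulum chaperones and related genes (CALR, HSPA5, PDIA4, HERPUD1, HSP90B1, DNAJC3 and PDIA6), by 0.63, 0.50, 0.40, 0.32, 0.23, 0.19 and 0.16 on the log2 scale.

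Hypoxia and glycolysis genes fell in 18 of 23 tested members, rose in 3 and did not pass in 2 (median log2 change -0.42, camera adjusted p = 0.000425, but adjusted p = 0.0780 with an estimated correlation). CA9, a carbonic anhydrase, fell from 5.15 ± 0.654 to 0.224 ± 0.111 FPKM and ADM, which encodes adrenomedullin, from 11.4 ± 0.380 to 3.83 ± 0.320 FPKM. VEGFA, the angiogenic growth factor, rose from 2.80 ± 0.0480 to 15.2 ± 0.225 FPKM, and PFKP and SLC2A3 rose by 0.20 and 0.20 on the log2 scale. Cholesterol and fatty acid synthesis genes fell in 13 of 22 tested members, rose in 2 and did not pass in 7 (median log2 change -0.16, camera adjusted p = 0.0296, but adjusted p = 0.121 with an estimated correlation). SREBF1, a transcription factor of lipid synthesis, fell from 26.8 ± 1.30 to 11.7 ± 0.535 FPKM. ACLY, which makes cytosolic acetyl-CoA, rose from 166 ± 2.24 to 313 ± 0.922 FPKM and SQLE rose by 0.21 on the log2 scale. The lipid list no longer passed with a filter of FPKM at least 5 (adjusted p = 0.0736), and after scaling to a fixed sum 6 members rose and 10 fell, with a median of -0.08.

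Proliferation genes changed little. Of 31 tested members 4 rose, 16 fell and 11 did not pass (median log2 change -0.09, camera adjusted p = 0.366), and adjusted over the list alone 5 rose and 16 fell. After scaling to a fixed sum 14 rose and 7 fell, with a median of 0.02, so the list has no direction that holds under every scaling. MKI67, the Ki-67 gene, was at 37.6 ± 0.962 and 39.2 ± 0.269 FPKM and did not pass (log2 change 0.06, SE 0.03, adjusted p = 0.0784), but passed after median-ratio scaling (adjusted p = 0.00905), after scaling to a fixed sum (adjusted p = 0.000450) and without control library 2 (adjusted p = 0.0329). PCNA, a DNA polymerase clamp, fell from 285 ± 6.15 to 232 ± 1.51 FPKM and AURKB, a mitotic kinase, rose from 29.9 ± 0.740 to 37.5 ± 1.69 FPKM. Of 14 tested cell cycle inhibitors and senescence genes 6 rose, 5 fell and 3 did not pass (median log2 change 0.03, camera adjusted p = 0.462), and adjusted over the list alone 7 rose and 5 fell. The median was 0.08 after median-ratio scaling and 0.16 after scaling to a fixed sum, with 7 up and 4 down. IGFBP7, an insulin-like growth factor binding protein, rose from 42.1 ± 0.639 to 198 ± 0.701 FPKM, and GADD45B rose by 1.45 on the log2 scale. GDF15, the member with the largest change, fell by 2.74 on the log2 scale, and IGFBP3, another such binding protein, fell from 169 ± 0.603 to 88.0 ± 2.00 FPKM.

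In the list of airway, basal and mucous epithelial genes all 5 tested members fell (median log2 change -2.78, camera adjusted p = 0.000543). With an estimated correlation the list did not pass (adjusted p = 0.0755). Its basal members KRT5, KRT14, KRT15, KRT17 and TP63 were below the expression filter, so the fall does not cover basal genes. Fitted with no filter, TP63 rose from 0.259 to 0.897 FPKM (adjusted p = 0.00119). In that fit KRT17 rose to 0.151 and KRT14 to 0.0416 FPKM (adjusted p = 0.0164 and 0.0232), while KRT5 and KRT15 did not pass. MUC5B (chromosome 11, 1223066 to 1262172), a gel-forming mucin at a pulmonary fibrosis risk locus, fell from 6.95 ± 0.348 to 0.139 ± 0.0380 FPKM. MUC5AC fell from 6.11 ± 0.357 to 0.0362 ± 0.00753 FPKM and SPDEF, a transcription factor of mucous cells, from 3.92 ± 0.0922 to 0.0109 ± 0.0188 FPKM. Of 7 tested alveolar epithelial genes 1 rose, 4 fell and 2 did not pass (median log2 change -0.34, camera adjusted p = 0.135). FOXA2, a lung epithelial transcription factor, fell from 16.7 ± 0.286 to 5.47 ± 0.519 FPKM and CAV1, which encodes caveolin, fell by 0.85 on the log2 scale, while ETV5 rose by 0.12 on the log2 scale. SFTPC, a surfactant protein gene, was at 0.0137 ± 0.0237 and 0.00260 ± 0.00451 FPKM, and NKX2-1, a lung lineage transcription factor, was listed at 0 in the 6 libraries.

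Genes at pulmonary fibrosis risk loci or of familial disease rose in 7 of 26 tested members, fell in 12 and did not pass in 7 (median log2 change -0.06, camera adjusted p = 0.784), while after scaling to a fixed sum 12 rose and 8 fell, with a median of 0.03. Besides MUC5B, STMN3 fell from 3.39 ± 0.558 to 1.15 ± 0.0746 FPKM and FKBP5, a co-chaperone of the glucocorticoid receptor, from 3.88 ± 0.104 to 1.60 ± 0.0380 FPKM. SPDL1, a spindle protein, rose from 24.4 ± 0.740 to 44.6 ± 0.247 FPKM. TERT, the telomerase reverse transcriptase, was below the expression filter at 0.844 ± 0.0812 and 0.529 ± 0.0210 FPKM. Of 16 tested genes of the DNA methylation machinery 8 rose, 1 fell and 7 did not pass (median log2 change 0.08, or 0.20 after scaling to a fixed sum, camera adjusted p = 0.0707). DNMT3B (chromosome 20, 32762385 to 32809356), a de novo methyltransferase, rose from 2.29 ± 0.0607 to 6.14 ± 0.170 FPKM and UHRF1, which recruits the maintenance methyltransferase, from 16.1 ± 0.151 to 21.5 ± 0.348 FPKM. DNMT1, the maintenance methyltransferase, was at 9.74 ± 0.480 and 9.35 ± 0.153 FPKM and did not pass (adjusted p = 0.284), and MBD4, a glycosylase, fell by 0.31 on the log2 scale.

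WNT pathway genes went both ways: of 18 tested members 6 rose, 9 fell and 3 did not pass (median log2 change -0.09, camera adjusted p = 0.446), and the median was 0.02 after scaling to a fixed sum. WNT5B, a ligand, rose from 0.283 ± 0.104 to 10.4 ± 0.176 FPKM, while RNF43, a ubiquitin ligase that removes WNT receptors, fell from 4.78 ± 0.105 to 0.409 ± 0.0489 FPKM. Of markers of other cell types few were expressed. Both tested fibroblast markers changed, COL1A1 upwards and TWIST2 downwards (camera adjusted p = 0.612). Of 2 tested endothelial markers, ESAM rose and EGFL7 fell, with log2 changes of 1.44 and -0.26 (camera adjusted p = 0.653). Of 2 tested immune markers, CD14 fell from 4.47 ± 0.234 to 0.443 ± 0.157 FPKM and CD68 did not pass (camera adjusted p = 0.273).

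The mitochondrially encoded mRNAs, read as a sign of RNA quality, rose in 1 of 13 tested members, fell in 9 and did not pass in 3 (median log2 change -0.13, camera adjusted p = 0.0667), but after quantile normalization 6 rose and 3 fell, with a median of 0.10. MT-CO1 went from 14329 ± 990 to 11221 ± 683 FPKM, and MT-CYB was the member that rose, by 0.12 on the log2 scale. The list passed without control library 2 (adjusted p = 0.0459) and without TGFβ1 library 3 (adjusted p = 0.0244). Heat shock and immediate early genes, which respond to handling, rose in 6 of 11 tested members, fell in 2 and did not pass in 3 (median log2 change 0.19, or 0.32 after scaling to a fixed sum, camera adjusted p = 0.0419, but adjusted p = 0.154 with an estimated correlation). JUN, a subunit of the AP-1 transcription factor, rose from 8.84 ± 0.650 to 35.6 ± 0.818 FPKM and IER3 from 36.2 ± 2.37 to 119 ± 6.78 FPKM, while FOS and HSP90AA1 fell by 0.65 and 0.22 on the log2 scale. The list did not pass without control library 3 (adjusted p = 0.0672), without TGFβ1 library 2 (adjusted p = 0.0577) or after quantile normalization (adjusted p = 0.0717).

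Camera with a preset correlation of 0.01 called 19 of the 31 lists, 12 up and 7 down, and 8 of these passed with an estimated correlation. The 8 were the SMAD2/3 target, mesenchymal, fibrillar matrix, collagen modifying, integrin, actin, aberrant basaloid and NRF2 lists, with adjusted p-values of 0.0486 to 0.0490. Several lists share members, so their calls are not independent. A lost call does not show that a list's members are correlated. The estimate was below 0.01 for the EMT factor (-0.0986), epithelial (-0.0165), protease (-0.0176) and cholesterol (-0.0463) lists. A lower correlation alone would have lowered their p-values. For the other lists that lost their call it was above 0.01. The preset and estimated tests therefore differ in more than the correlation.

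**Figure D4:**
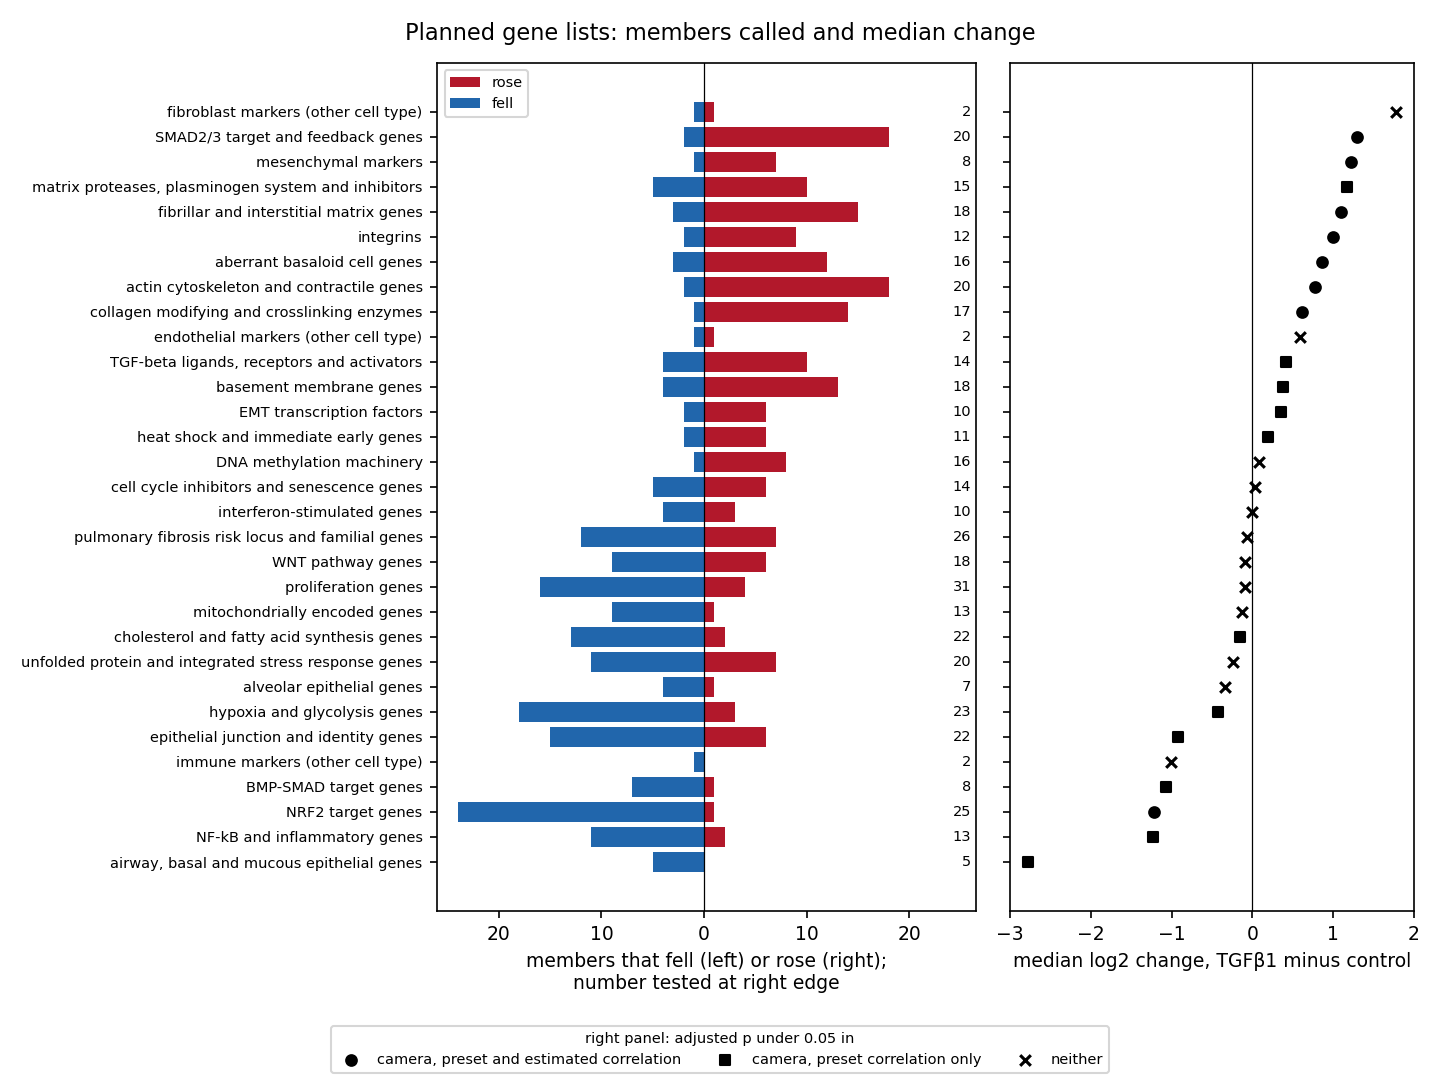
The 31 gene lists (y axis), with the number of members that fell or rose on the left and the median log2 change, TGFβ1 minus control, on the right, where the symbol gives the camera calls. Medians run from -2.78 for airway, basal and mucous genes to 1.77 for the 2 fibroblast markers, and those of the proliferation, WNT, interferon, pulmonary fibrosis risk and mitochondrial lists change sign with the scaling.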

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

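The single-transcript and mitochondrial settings were chosen after the results were seen. The count of 7490 changed genes stayed within 1.5 times of itself except where fewer genes were tested: with FPKM at least 5 (6685 genes), 4678 changed (2037 rose, 2641 fell) and 297 fell at least 2-fold. Among 1649 genes listed with 1 transcript, 646 changed (268 rose, 378 fell) and 128 did so at least 2-fold (67 rose, 61 fell). A smaller pseudocount widens folds near 0: 738 genes fell at least 2-fold with 0.1 and 775 with 0.01, of 1320 that changed so. Leaving out 1 library gave 6902 to 7039 changed genes (2840 to 2922 rose, 4017 to 4134 fell), 857 to 866 with a 2-fold change (391 to 396 rose, 461 to 472 fell) and 18 to 20 lists called. The study's test called 6701 genes. The fit with mitochondrial genes left out and the rest rescaled to a fixed sum called 7483, of which 49.8% rose. Scaling to a fixed sum with mitochondrial genes kept gave 60.4%. The excess of rises under that scaling therefore depended on the mitochondrial genes in the sum. Same-numbered samples correlated at 0.01, 0.07 and 0.02 in their deviations from the group means, and differently numbered ones at -0.05 to 0.03. Such small values cannot show whether the numbers pair the samples. The replicate block called 7370 genes.

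Of the 19 lists called, 8 passed with an estimated correlation, while fry, which asks another question, called 31. MT-ND4 reversed under quantile normalization, at 0.15, and MT-CO1 and MT-CO3 did not pass there; the cause was not tested. CCNE2 did not pass with no filter (adjusted p = 0.0517) or by the study's test (0.0520). DNA methylation and fibroblast lists passed with no filter (0.0144 and 0.0132), and the mitochondrial list with the block (0.0252). Depth is unknown, so what it limits was not assessed. Alternatives for counts were not run because only FPKM were analysed.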

Other observations

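The symbol families, the second NRF2 list and the tests of scaling, shared reads, mitochondrial mRNAs and ribosomal protein genes were chosen after the results were seen.

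Gene families were taken as all tested genes that share a symbol root, with at least 10 members. Some hold members of the gene lists, such as COL1A1, AKR1C1 and ALDH3A1, so their calls partly repeat those of the lists. Of 139 families, camera called 6, and 0 with an estimated correlation (adjusted p = 0.675 for each of the 6), while of 139 random families it called 0. Random families lack the correlation that members of real ones can have, so that 0 does not support the 6 calls. Collagen genes rose in 14 of 17 members and fell in 3 (adjusted p = 2.03e-05), and GALNT genes, which start O-linked glycosylation, rose in 8 of 12 and fell in 3 (adjusted p = 0.0437). Aldo-keto reductases fell in 10 of 12 and rose in 0 (adjusted p = 0.000263), and ALDH genes fell in 9 of 15 and rose in 1 (adjusted p = 0.0379). Mitochondrial ribosomal proteins of the large subunit fell in 34 of 51 and rose in 1 (median log2 change -0.19, adjusted p = 0.0143), and those of the small subunit fell in 19 of 29 and rose in 1 (median -0.22, adjusted p = 0.0149). After scaling to a fixed sum these medians were -0.10 and -0.14.

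Of 7 genes often used as references, GAPDH, ACTB, POLR2A and B2M passed and TBP, HPRT1 and RPLP0 did not. GAPDH fell by 0.54 on the log2 scale, from 1801 to 1234 FPKM, and ACTB rose by 0.64, from 766 to 1197 FPKM, and both kept their direction under the 3 scalings. HPRT1 passed under none of the 3 scalings (adjusted p = 0.858, 0.219 and 0.368), and TBP passed only after scaling to a fixed sum (adjusted p = 0.0253). RPLP0 had a log2 change of -0.01 (adjusted p = 0.484), which turned to 0.04, 0.11 and 0.10 after median-ratio, quantile and fixed-sum scaling and passed under the last 2 (adjusted p = 0.000700 and 0.000476). List members and named genes below the expression filter were fitted with no filter, and those given next were chosen after their values were seen. HEY1, BMP2, TP63, KRT17 and KRT14, which rose in that fit, are given at their lists. INHBA, which encodes an activin subunit, went from 0.0158 to 0.871 FPKM (adjusted p = 0.000259), SNAI2 from 0.0903 to 0.945 FPKM (adjusted p = 0.000408), CDH11 from 0.0149 to 0.657 FPKM (adjusted p = 0.000138) and TERT from 0.844 to 0.529 FPKM (adjusted p = 0.0154). Some members went against their lists in that fit. The integrin genes ITGB2, ITGB8 and ITGA10 fell (adjusted p = 0.00470, 0.00516 and 0.0461). Among NF-kB and inflammatory genes, IL1A rose from 0.0342 to 0.591 FPKM (adjusted p = 0.00107). IL6 also rose (adjusted p = 0.0214), while IL1B and LCN2 fell (adjusted p = 0.0138 and 0.0186).

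NRF2 targets fell with a median log2 change of -1.22, in a line known to carry a KEAP1 mutation that keeps NRF2 active. Scaling is argued against, since the highest median over 3 scalings was -1.10, and so are reads shared between paralogs, since the median was -0.94 over 19 members with 1 per symbol root and no AKR1 gene. A second list that shares no member with the first, fixed before its values were seen, had a median of -0.61, with 19 of 22 tested members down and 2 up (camera p = 3.07e-06, 0.0240 with an estimated correlation). NFE2L2, which encodes NRF2, fell by 0.44 and KEAP1 by 0.16 on the log2 scale. A lower output of the NRF2 programme under TGFβ1 is a hypothesis, and whether NRF2 protein or its activity changed was not measured.

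Mitochondrial ribosomal RNAs fell more than mitochondrial mRNAs: MT-RNR2 went from 9181 ± 75.8 to 4955 ± 259 FPKM and MT-RNR1 from 820 ± 150 to 460.4 ± 90.9 FPKM, a median log2 change of -0.86. A lower share of all mitochondrial RNA would lower both alike, so alone it would not give this gap. The 13 protein-coding genes had a median of -0.13 (range -0.35 to 0.12), which restates the pattern and is not an independent test. Less carry-over of RNA without a poly(A) tail cannot be told apart from a change in the cells: 11 other such RNAs had a median of -0.21 (SE 0.15), too wide to decide, and mostly histone genes, some of which also make polyadenylated mRNA. The 22 mitochondrial transfer RNAs, which are not in that set, had a median of -0.25 (0 rose, 8 fell, range -1.17 to 0.31), which does not settle carry-over.

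Ribosomal protein genes, which cells make in similar amounts, spanned 5.06 to 712 FPKM over 76 genes. For genes with several transcripts, 25.5% of values under 2 FPKM became whole within 0.01 in units of the 6th decimal, not in reads, when multiplied by the length of the union of the gene's exons, against 3.15% with shuffled lengths and 2% by chance. This is consistent with gene values spread over the union of exons, which lowers genes with long rare transcripts. Poor recovery of short mRNAs stays open: across these genes FPKM had a Spearman rho of -0.29 with the longest coding transcript (permutation p = 0.0134, genes are not independent), but that length rises with the union of exons (rho 0.83), so the sign is built in. Levels may therefore not be compared between genes, while a comparison of 1 gene between groups is less affected.

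There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, and the real one was the 1 split with a result as large in each case. It gave 7490 changed genes against 1 in the highest other split, 862 against 1 for 2-fold changes and 19 against 9 for gene lists. Every other split mixes control and TGFβ1 libraries on both sides, which puts the group difference into the spread. Low gene counts there were therefore built in, and the splits do not measure chance.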
